A study of Rattus norvegicus with 28 samples.

How the data were processed

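RNA of 28 striatal samples of male rats was sequenced by the submitters in single-end reads of 75 nt in 2 runs, from a stranded mRNA library kit, per the labels' protocols. Which library was in which run is not given in the sources used here. The labels name each library by a number of its own, and nothing there says more about separate animals, so p-values measure the spread between these libraries. No replicate number is shared between groups, so no paired analysis was made.

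Reads were aligned with STAR 2.6.1a to Rnor_6.0 and assigned with featureCounts of Subread 1.6.3, with DESeq2 1.22.2 also named, per the submitters' processing notes. The strand setting of the counting is not given in the sources used here, so genes overlapping on opposite strands are uncertain. The deposited table holds RPKM values, written with decimal commas, for 39538 genes, including the human TOR1A transcript as a row of its own. The length behind the deposited RPKM was the span of the gene with its introns, as tested on every gene. RPKM times length in kilobases gave values with the same sum in every library, which are called RPM (reads per 1000000 reads assigned to genes) here. These values were whole multiples of 1 step per library within a tolerance of 0.02 for 100% of values, so whole reads were computed from them. The libraries held 29151455 to 38407359 assigned reads, and a count of 0 allows at most 0.103 RPM in the library of lowest depth, for counting error only. The unit of the table was recorded as other, because decimal commas could not be read by the unit check, and the values were treated as RPKM.

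All 28 libraries entered 1 limma fit (limma 3.58.1, R 4.3.3) of log2 (RPKM + 0.1) on the 4 groups, with moderated variances that follow the mean. Genes with an RPKM of at least 0.5 in at least 6 libraries were tested, 11374 in all. Because the RPKM are per span, this minimum removes long genes of moderate level. The 6 contrasts were TG against wt in naive rats, in crush rats and averaged over both, crush against naive in wt and in TG rats, and the interaction. Calls were made at an adjusted p under 0.05 (Benjamini-Hochberg).

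Of 45 gene lists fixed before the data were examined, the 43 with at least 5 tested genes were tested by camera with a preset correlation of 0.01, with an estimated correlation, and by fry. Of 1136 list entries, 1135 were matched to the table. Tor1a, the human transcript and RGD1305178 were also compared by two-sided exact permutation tests over libraries. RGD1305178 was added to these after its values were seen. Genes were named by a rule fixed beforehand: per contrast, up to 12 higher and 12 lower calls of largest change with a mean RPKM of at least 1 and a true symbol, the 5 genes of lowest p where fewer than 5 passed, up to 4 members of lowest p from each list with a call, and Tor1a. RGD1305178, LOC680517, Pld6, Tgm2, Parvb and Per2 in the comparisons where the rule leaves them out, and Arntl, were chosen after their values were seen.

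The fit was tested on simulated counts with known changes at the real depths and means. In the simulated naive comparison of genotypes, over 11349 genes, 40% of genes changed 1.2-fold, 87.8% of those changed 1.5-fold and 98% of those changed 2-fold were recovered, with 10 false calls among 171. In the simulated comparison of crush and naive TG rats, over 11349 genes, the shares were 46%, 88% and 94%, with 8 false calls among 172. The simulation draws genes independently, so it carries no shared variation in tissue composition.

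Alternatives planned beforehand were pseudocounts of 1 and 0.01, no filter, a stricter filter of RPKM 1 in 14 libraries, median-of-ratios rescaling, quantile normalization, fits on the compared groups alone, array weights, robust variances, 1 surrogate factor, a fold of at least 1.2, and leaving out each library in turn. Chosen after seeing the data were RPM with a minimum and pseudocount of 0.5, limma-voom on the whole reads, the mean level of the spiny neuron markers as a covariate, and leaving out 5 libraries with over 20 RPM of Slc17a7. The surrogate factor was the main axis of the variation left within the 4 groups. It is therefore uncorrelated with the groups, leaves each log2 change as it was and alters only its error. The alternatives for deposited raw counts were not run, because the table holds RPKM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and permutation tests used scipy 1.17.1.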

Results

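Gene expression was measured by RNA sequencing in the striatum of male rats, in 28 libraries of 4 groups. The transgenic (TG) rats model DYT-TOR1A dystonia, an inherited movement disorder caused by a small deletion in TOR1A, which encodes the endoplasmic reticulum ATPase torsinA. Wild-type (wt) and TG rats were either naive or had received a crush injury of the right sciatic nerve, and the labels give 12 weeks after injury as the time of sampling. There were 8 wt naive, 6 wt crush, 8 TG naive and 6 TG crush libraries, with 29151455 to 38407359 reads assigned to genes in each. The questions were which genes differ between TG and wt rats, with or without the injury, and which differ between injured and naive rats of each genotype.

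The human TOR1A transcript separated the genotypes in every library. It averaged 138 ± 4.81 RPM (RPM, reads per 1000000 reads assigned to genes; SD, n = 8) in TG naive and 131 ± 14.1 (SD, n = 6) in TG crush rats, against 0.227 ± 0.324 (SD, n = 8) in wt naive and 0.104 ± 0.172 (SD, n = 6) in wt crush rats. The lowest TG library held 102 RPM and the highest wt library 0.972. In RPM, which is not corrected for length, the human transcript stood 6.31 times above rat Tor1a in TG naive and 6.19 times above it in TG crush rats. In the exact two-sided permutation test over libraries p was 0.000155 in the naive arm and 0.00216 in the crush arm, each the smallest value the test can give. Rat Tor1a (chromosome 3, 9800322 to 9807318, Rnor_6.0) did not pass the test: its log2 change was -0.04 in the naive arm (exact permutation p = 0.244) and -0.06 in the crush arm (exact permutation p = 0.511).

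**Figure D1:**
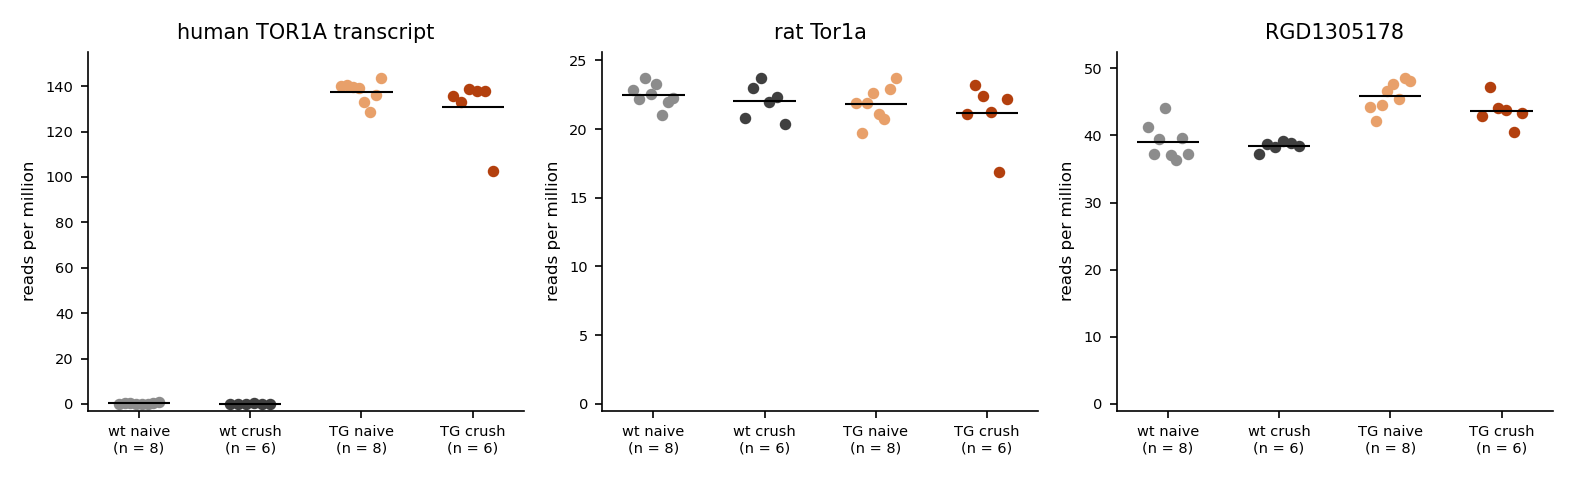
RPM of the human TOR1A transcript, rat Tor1a and RGD1305178 in each library, by group, with points for libraries and lines for group means. The human transcript lies between 102 and 144 RPM in TG and at most at 0.972 in wt libraries, rat Tor1a lies at similar levels in the 4 groups, and the mean of RGD1305178 is 45.9 in TG naive against 39.0 in wt naive rats.

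In naive rats, TG and wt striatum differed in few genes. Besides the human transcript, RGD1305178, Zfp180 and LOC680517 were higher in TG rats, and the clock repressors Nr1d1 and Nr1d2 were lower. Nr1d1 fell by 0.46 (SE 0.08) and Nr1d2 fell by 0.35 (SE 0.05) on the log2 scale, and Zfp180, a zinc finger gene, rose by 0.30 (SE 0.06). RGD1305178, whose current symbol is C3h9orf78, is the gene next to Tor1a (chromosome 3, 9813914 to 9822222, Rnor_6.0) and rose by 0.23 (SE 0.04, limma adjusted p = 0.00804). LOC680517, currently annotated as a pseudogene of Hnrnpm, rose by 0.57 (SE 0.11), and its reads cannot be told from those of its parent gene with certainty. In all, 6 of 11374 genes passed limma's test at an adjusted p under 0.05, 4 of them higher and 2 lower in TG rats, and 534 had an unadjusted p under 0.05 where 568.7 are expected by chance. Without 5 libraries high in the cortical gene Slc17a7, a choice made after seeing the data, the human transcript and Nr1d2 were the 2 genes that passed. Lost were the calls of Nr1d1 (log2 change -0.48, adjusted p = 0.21), Zfp180 (0.28, adjusted p = 0.0916), RGD1305178 (0.20, adjusted p = 0.599) and LOC680517 (0.49, adjusted p = 0.628).

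Of the 15 clock genes measured, 2 were lower and 13 did not pass in this comparison. Adjusted over the list alone, 7 were lower and 1 was higher. Dbp, a transcription factor driven by the clock, had a log2 change of -0.42 (adjusted p = 0.0502), and Ciart, a clock repressor, one of -0.67 (adjusted p = 0.119). As a set the clock genes were lower by camera with a preset correlation (adjusted p = 1.43e-08), with an adjusted p = 0.187 with an estimated correlation. The other 4 lists called were those for the unfolded protein response, heat shock proteins, immediate early genes and spiny projection neurons. They were higher by the preset test with no single member passing, and their adjusted p was 0.975 with an estimated correlation. The torsin genes and the genes of inherited dystonia had median log2 changes of -0.01 and -0.04, with adjusted p values of 0.963 and 0.709 by the preset test.

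After nerve crush, the human transcript and the histone gene Hist3h2a were the genes that passed between TG and wt rats. Hist3h2a was lower by a log2 change of -0.24 (SE 0.04, adjusted p = 0.0484). Of the genes next in order of p, Pld6, a mitochondrial phospholipase, had a log2 change of -1.01 (adjusted p = 0.265), Cd93, an endothelial receptor, one of -0.51 (adjusted p = 0.304), and LOC679594 one of -0.48 (adjusted p = 0.304), so none of the 3 passed. The call of Hist3h2a was lost with a pseudocount of 0.01, median-of-ratios rescaling, quantile normalization, the crush groups fitted alone, array weights and a fold of at least 1.2, all planned beforehand. It was also lost under the 4 alternatives chosen after seeing the data, RPM (adjusted p = 0.131) among them, and with a single library left out in 20 of 28 cases. With p adjusted again without the human transcript, a test chosen after seeing the data, 0 genes passed. With 1 surrogate factor, which leaves each log2 change as it was, 163 genes passed, 29 higher and 134 lower. There were 849 genes with an unadjusted p under 0.05 where 568.7 are expected by chance, and this count moved both ways with single libraries. The excess was gone without TG crush replicate 223 (437 genes) and without wt crush replicate 206. It was also gone with the spiny neuron level as a covariate, chosen after seeing the data (494 genes). The count rose to 1162 without TG crush replicate 214 and to 1139 without TG crush replicate 219.

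Between the crush groups 17 of 43 lists were called by the preset test and 0 with an estimated correlation or by fry. The 17 markers of spiny projection neurons had a median log2 change of -0.27 in TG crush against wt crush, and none passed singly (adjusted p = 3.31e-05 preset, adjusted p = 0.75 with an estimated correlation). Markers of microglia, astrocytes, myelin, and endothelium with pericytes were higher by the preset test. So were blood genes, genes of the interferon and unfolded protein responses, and transcripts of the mitochondrial genome. Lists for direct pathway neurons, dopamine, calcium, immediate early genes, proteasome, glycolysis and nuclear respiratory chain were lower. The genes of inherited dystonia were lower too (median log2 change -0.08, adjusted p = 0.0481 preset). No member of these lists passed singly, and each list had an adjusted p = 0.75 with an estimated correlation. The mean log2 level of the spiny neuron markers was 3.11 ± 0.07 (SD, n = 6) in wt crush and 2.84 ± 0.31 (SD, n = 6) in TG crush libraries. TG crush replicate 223 was lowest in its group at 2.35 and had the largest mitochondrial share, 18.5%. Without it the TG crush mean was 2.94, and the gap to wt crush went from 0.27 to 0.17. The lists were not tested without this library.

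Averaged over both arms, RGD1305178 was higher in TG rats by 0.20 (SE 0.03, adjusted p = 0.00104), while Nr1d1 fell by 0.37 (SE 0.06) and Pld6 fell by 0.91 (SE 0.14). With the human transcript these were the 4 genes called, and LOC108348112, next by p, did not pass (adjusted p = 0.106). Pld6 was at a low level (mean RPKM 0.438). It did not separate every library, since TG naive replicate 189 stood at 0.903 RPKM, above the highest wt library at 0.687. In the exact permutation test over libraries RGD1305178 differed in the naive arm (p = 0.000311) and in the crush arm (p = 0.00216, the smallest value possible there). Across 11373 genes, without the human transcript, the genotype changes in naive and in crush rats had a Pearson r of -0.16 and a Spearman rho of -0.13, and 0 genes other than the human transcript were called in both arms. Genes are not independent replicates, and the jackknife standard error of r over libraries was 0.252. Without the libraries high in Slc17a7 the human transcript alone passed for the average, and the calls of RGD1305178 (log2 change 0.19, adjusted p = 0.0539), Nr1d1 (-0.37, adjusted p = 0.0727) and Pld6 (-0.91, adjusted p = 0.0539) were lost. For the average 12 of 43 lists were called by the preset test, and 0 with an estimated correlation or by fry. The unfolded protein response list was higher (median log2 change 0.08, preset adjusted p = 4.97e-07), as in each arm. The interferon response list was higher too (0.11, preset adjusted p = 5.61e-07). No member of either passed singly, and both had an adjusted p = 0.882 with an estimated correlation. The clock, proteasome and glycolysis lists were lower by the preset test.

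In wt rats, nerve crush went with higher clock genes and with lower levels of genes such as Tgm2, Mmp14, Parvb and Klhdc7a. Ciart rose by 1.07 (SE 0.16), Dbp by 0.51 (SE 0.09), Per2 by 0.52 (SE 0.11), Nr1d2 by 0.35 (SE 0.05), Bhlhe41 by 0.34 (SE 0.06) and Cipc, a repressor of the CLOCK protein, by 0.20 (SE 0.05). Fgfr1op2 rose by 0.29 (SE 0.06). Among the genes that fell were the transglutaminase Tgm2 (log2 change -0.61), the matrix protease Mmp14 (-0.56), the focal adhesion gene Parvb (-0.49), Klhdc7a (-0.66), the sulfotransferase Sult1a1 (-0.69), the kinesin Kif21b (-0.70), Fxyd5 (-0.61), the small GTPase gene Diras3 (-0.50), Fam107a (-0.45), the adaptor Shc1 (-0.36) and the ribosomal protein gene Rpl30 (-0.36). Gh1, the growth hormone gene of the pituitary, rose by 4.26 (SE 0.95), between 0.349 and 32.5 RPM in the wt crush libraries. The pituitary gene Prl stood at 0 to 0.345 RPM in wt naive and 0.0268 to 6.45 in wt crush libraries, so traces of pituitary tissue are not excluded. In limma's test 36 of 11374 genes passed, 10 higher and 26 lower. Among the lower, LOC108349022, LOC108353423 and LOC108353424 had the same mean RPKM (4.94), log2 change (-0.34) and SE (0.08). They cannot be taken as separate signals.

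Of the 15 clock genes, 5 rose and 10 did not pass in wt rats, and 12 rose and 1 fell when adjusted over the list alone. The clock list passed with the preset correlation (adjusted p = 1.24e-14) and with an estimated correlation (adjusted p = 0.0196). Of 76 cytosolic ribosome genes, 1 fell and 75 did not pass, 59 were lower when adjusted over the list alone, and the list was lower by the preset test, with an adjusted p = 0.49 with an estimated correlation. The 17 spiny neuron markers had a median log2 change of 0.40, among them Ppp2r2a (0.42) and Pde1b (0.42), and the 18 astrocyte markers were lower as a set, among them Gjb6 (-0.32), with no member passing and an adjusted p = 0.49 for both lists with an estimated correlation. Microglial markers such as Tyrobp (-0.54, adjusted p = 0.0857) were lower as a set by the preset test, with an adjusted p = 0.514 with an estimated correlation. The spiny neuron level was 3.11 ± 0.07 (SD, n = 6) in wt crush against 2.75 ± 0.37 (SD, n = 8) in wt naive libraries. The cortical gene Slc17a7 was above 20 RPM in 3 of the wt naive and 0 of the wt crush libraries, and without these 3 the wt naive level was 2.90 ± 0.36 (SD, n = 5) and the gap went from 0.36 to 0.21.

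The wt count depended on the model and on single libraries. With the spiny neuron level as a covariate, chosen after seeing the data, 6 genes passed. Genes with an unadjusted p under 0.05 went from 2506 to 622, where 568.7 are expected by chance. Because the level differed between the wt groups, the covariate may also take up effects of the injury that go along with it. With array weights 1348 passed, and with a surrogate factor that follows that level within groups (absolute r 0.966) 1682 did. By construction that factor does not differ between the groups, so it cannot remove a difference in composition between them. Without the 5 libraries high in Slc17a7, 9 genes passed. Leaving out 1 library gave between 9 (without wt crush replicate 210) and 304 genes (without wt naive replicate 196).

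In TG rats, nerve crush went with 121 genes higher and 371 lower among 11374 in limma's test. Genes with an unadjusted p under 0.05 numbered 2478 in TG and 2506 in wt rats, where 568.7 are expected by chance. The larger number of calls thus does not show a broader difference in TG rats. With 1 surrogate factor 1219 genes passed in TG rats and 1682 in wt rats. Clock genes were among the increases. Ciart rose by 1.91 (SE 0.16), Dbp by 0.98 (SE 0.09), Nr1d2 by 0.81 (SE 0.05), Per3 by 0.77 (SE 0.07), Bhlhe41 by 0.56 (SE 0.06), Bhlhe40 by 0.55 (SE 0.10), Nr1d1 by 0.54 (SE 0.09) and Per1 by 0.39 (SE 0.11). Other increases included Rbm3, an RNA-binding protein induced by cold (0.81), the Ras-like gene Rasl10a (0.65), the Notch pathway gene Nrarp (0.49) and Rps2-ps2, a ribosomal pseudogene that may share reads with Rps2 (0.95).

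**Figure D2:**
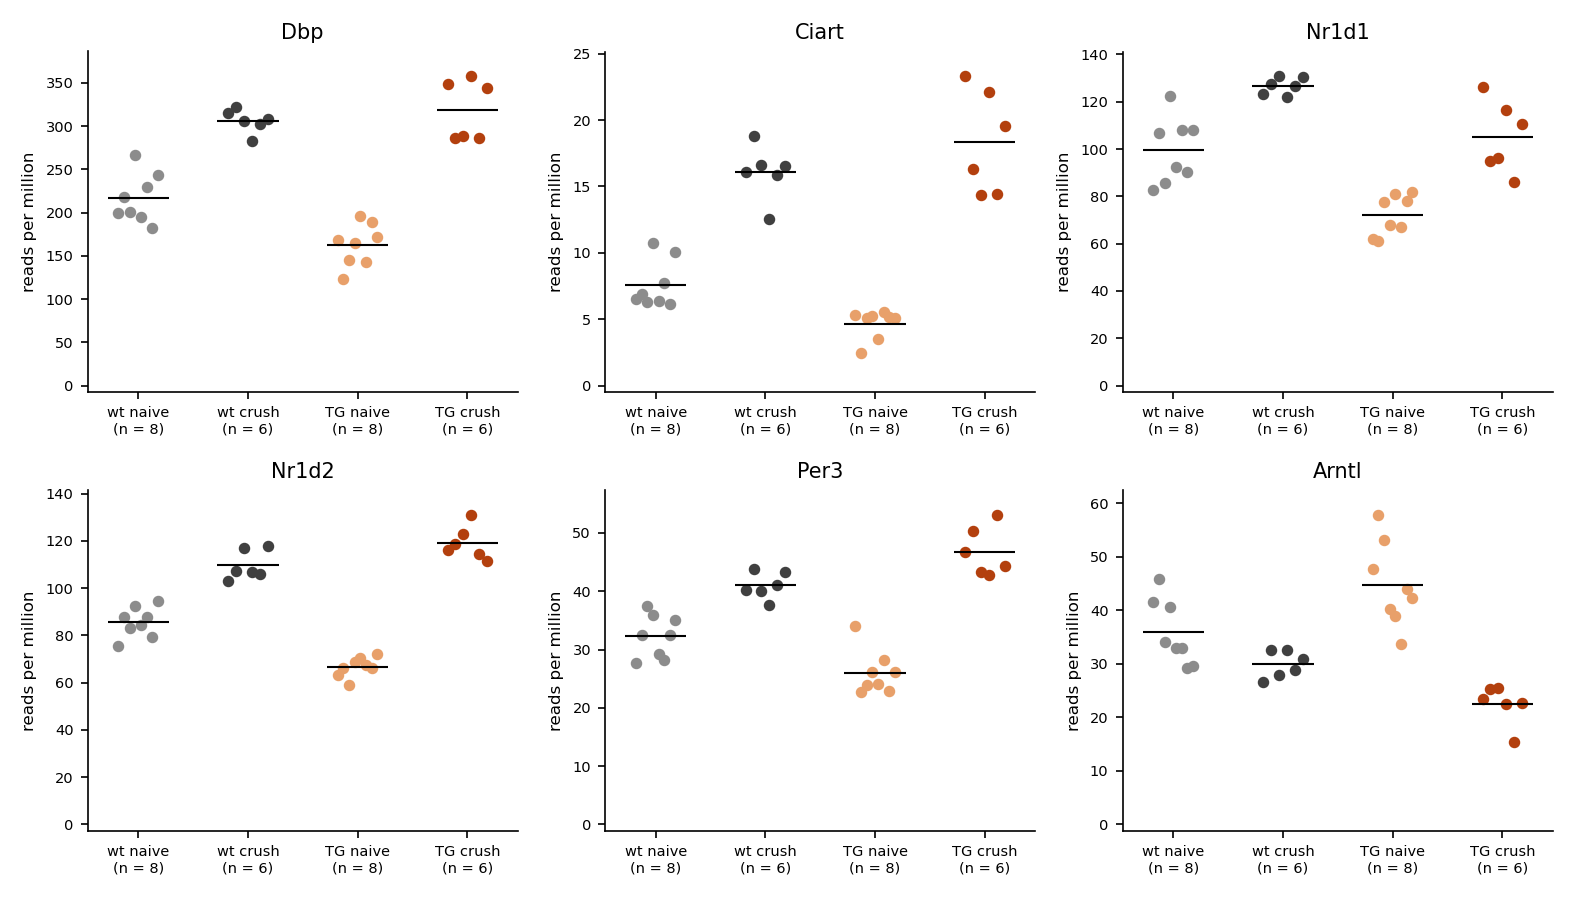
RPM of 6 clock genes in each library, by group, with points for libraries and lines for group means. Dbp averages 163 in TG naive and 319 in TG crush libraries, and Arntl, which peaks in the opposite phase, averages 44.7 and 22.4.

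Of the 15 clock genes measured, 12 rose, 2 fell and 1 did not pass in TG rats. The list passed with the preset correlation (adjusted p = 5.49e-21) and with an estimated correlation (adjusted p = 0.00224). Arntl, an activator of the clock that is below the RPKM minimum, fell by 0.98 (SE 0.11, adjusted p = 3.64e-06) on the scale of RPM.

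Among the genes that fell in TG rats were Mir132 (log2 change -1.46, and -0.64 on the RPM scale), the matrix protease Mmp14 (-1.18), the cell cycle inhibitor Cdkn1a (-1.13), the endothelial receptor Cd93 (-1.09), Klhdc7a (-1.06), the neuronal noncoding RNA Bc1 (-0.90), the microglial receptor Gpr84 (-0.72), the interferon-induced gene Bst2 (-0.63) and the neuropeptide precursor Vgf (-0.58). Tgm2 fell by 1.23 and Parvb by 0.72. In the matrix list Mmp14 and the basement membrane collagen Col4a1 (-0.50) fell, and the complement gene C1qb (-0.36) fell among the microglial markers.

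Of 43 lists, 6 were called in TG rats by the preset test, and of these the clock list alone passed with an estimated correlation. Cytosolic ribosome genes, nuclear respiratory chain genes and astrocyte markers were lower, and blood genes and transcripts of the mitochondrial genome were higher. Of 76 cytosolic ribosome genes, 14 fell and 62 did not pass, among them Rpl35 (log2 change -0.32) and Rps15 (-0.29), and 53 were lower when adjusted over the list alone, with an adjusted p = 0.961 with an estimated correlation. Of 75 nuclear respiratory chain genes, 5 fell and 70 did not pass, among them Ndufa8 (-0.22) and Uqcr10 (-0.19), with an adjusted p = 0.961 with an estimated correlation. Mt2A (-0.47) and Mt3 (-0.26), which bind metals, fell, as did the endoplasmic reticulum chaperones Calr (-0.25) and Hsp90b1 (-0.26). In the integrated stress response Atf5 (-0.33) fell and Ppp1r15b (0.24) rose. Grik5, a kainate receptor subunit, rose by 0.38, and the neurotrophic receptor Cntfr fell by 0.26. Tor1aip1, the nuclear envelope cofactor of torsinA also called LAP1, fell by 0.17 (SE 0.05, adjusted p = 0.0437), and Banf1, which links chromatin to the envelope, fell by 0.23 (SE 0.06). Of the 13 transcripts of the mitochondrial genome 11 had a positive log2 change, with a median of 0.12 (adjusted p = 0.0278 preset, adjusted p = 0.961 with an estimated correlation). The 5 blood genes had a median log2 change of 0.87 (adjusted p = 0.0135 preset, adjusted p = 0.961 with an estimated correlation) and the 18 astrocyte markers one of -0.16 (adjusted p = 0.0278 preset, adjusted p = 0.961 with an estimated correlation). No member of these 3 lists passed singly. The spiny neuron level was alike in TG crush, at 2.84 ± 0.31 (SD, n = 6), and TG naive libraries, at 2.85 ± 0.25 (SD, n = 8).

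The split between higher and lower calls depended on scaling. With median-of-ratios rescaling 196 genes were higher and 205 lower, and without the libraries high in Slc17a7, a choice made after seeing the data, 126 genes passed. Fitted on the TG libraries alone, 75 genes passed, and leaving out 1 library gave between 164 (without TG crush replicate 220) and 1074 genes (without TG crush replicate 223).

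**Figure D3:**
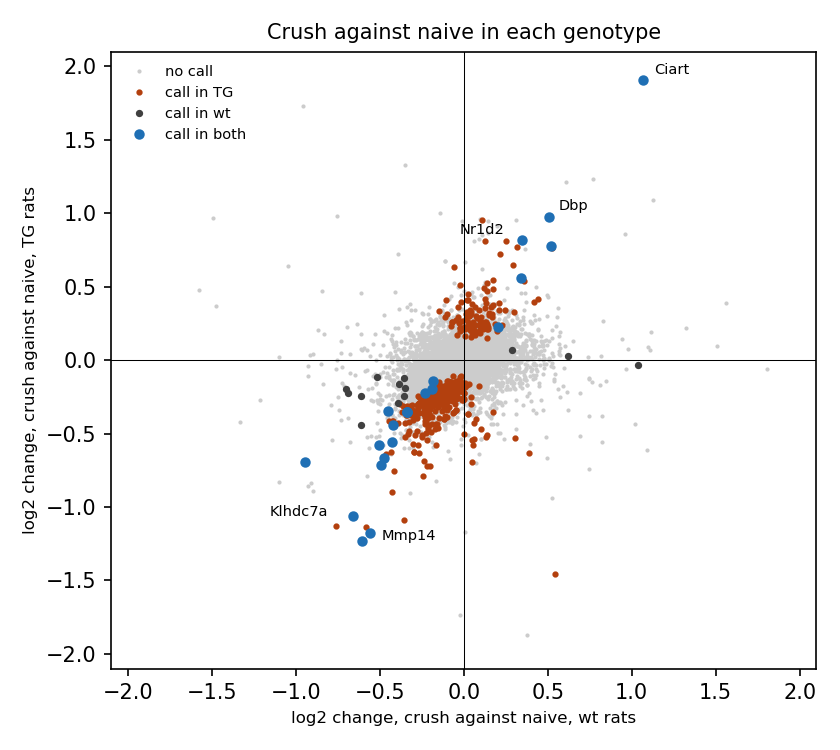
Log2 change of each tested gene, crush against naive, in wt rats (x axis) and TG rats (y axis), with points for genes colored by which test called them. Of 11373 genes without the human transcript, 4 lie outside the axes, and 22 were called in the same direction in both genotypes.

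The differences between crush and naive rats overlapped between the genotypes. The comparisons share no library, though they share the gene variances of 1 fit. In both, 22 genes were called in the same direction, against 0.955 expected from independent lists. Clock genes such as Ciart and Dbp are among them. The overlap cannot tell the injury from an unlabelled difference shared by both crush groups, such as the time of collection. Across genes the Pearson r was 0.34 and the Spearman rho 0.46. Of the 492 genes called in TG rats, 444 had the same sign in wt rats, and of the 36 called in wt rats 35 had the same sign in TG rats.

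In limma's test of the interaction 1 gene passed, Nr1d2, and with 1 surrogate factor 167 genes did, 44 higher and 123 lower. The change of Nr1d2 was larger in TG rats by 0.46 (SE 0.07, adjusted p = 0.00604): it averaged 66.6 ± 4.13 RPM (SD, n = 8) in TG naive, 119 ± 7.02 (SD, n = 6) in TG crush, 85.6 ± 6.41 (SD, n = 8) in wt naive and 110 ± 6.28 (SD, n = 6) in wt crush libraries. Tgm2 (-0.62) and Cd93 (-0.74), next in order of p with LOC680517 and Hist3h2a, had adjusted p values of 0.133 and did not pass. Without the libraries high in Slc17a7, 0 genes passed limma's test of the interaction, Nr1d2 included, with 385 at an unadjusted p under 0.05. The 167 calls came only with the surrogate factor, which leaves each log2 change as it was, and every other setting gave at most 2 genes. Whether other genes respond differently in the genotypes stays open. The clock list was higher by the preset test (adjusted p = 0.000204), with an adjusted p = 0.819 with an estimated correlation and 14 of its 15 genes not passing. The spiny neuron markers had a median log2 interaction of -0.35 by the preset test, with an adjusted p = 0.819 with an estimated correlation.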

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

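The tests of opposite clock phases, of the neighbourhood of Tor1a, of the relation to the human transcript and of the splits without that transcript were chosen only after the results were seen. The first was moved to RPM when Arntl turned out to be below the RPKM minimum. The tests with the spiny neuron level, the within-group clock slope and the other splits of the libraries were set before their values were computed, although a surrogate factor that follows the spiny neuron level (absolute r 0.966) had been examined before.

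Clock genes differed between crush and naive rats of both genotypes. The share of spiny projection neurons in the tissue is argued against for TG rats by its alike level, 2.84 in TG crush and 2.85 in TG naive libraries. With that level as a covariate 100% of the 14 clock genes called there were still called. This adds nothing, since an alike level leaves the covariate little group difference to remove. The time of day of tissue collection remains a candidate explanation: genes of the Dbp phase and of the Arntl phase moved apart by 1.19 on the log2 scale in TG rats, and Arntl and Dbp passed in opposite directions on the scale of RPM. In wt rats the arms differed by 0.52, with a mean of -0.05 in the Arntl phase, and Arntl did not pass (adjusted p = 0.224), so opposite phases were not shown there. The labels give no collection times, so a lasting effect of the injury on the clock, which the design names, stays open and was not tested apart from it. The same index differed between naive groups, at 1.10 ± 0.21 (SD, n = 8) in wt and 0.57 ± 0.18 (SD, n = 8) in TG libraries, so the lower Nr1d1 and Nr1d2 in TG naive rats may have the same source.

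Outside the clock list, 478 genes were called between crush and naive TG rats. All 478, or 100%, were still called with the spiny neuron level as a covariate. That result cannot decide, since the level was alike in TG crush (2.84) and TG naive libraries (2.85) and left the covariate little to remove. The alike level itself argues against a different mean share of these neurons as their whole cause in TG rats. For wt rats this says nothing, since the level differed between the groups there: the count went from 36 to 6 with the level as a covariate. The 1682 calls with the surrogate factor do not bear on it, since that factor cannot take up a difference between groups. Time of day cannot be told apart from the injury for these genes: their slopes on the clock index within groups had an r of -0.31 across genes with the crush change, and 90 of 100 permutations within groups gave a value as high. Other unlabelled differences between the groups, and the injury itself, stay open and were not tested.

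RGD1305178, beside Tor1a, was higher in TG rats in the naive arm and on average, and without the libraries high in Slc17a7 it passed in neither (log2 change 0.20, adjusted p = 0.599 in the naive arm, and 0.19, adjusted p = 0.0539 on average). A change of the whole neighbourhood is argued against, since the 7 other tested genes within 200 kb had a median log2 change of -0.019 and none passed. Reads from a human copy of this gene, if the transgene carried one, could align to the rat gene, and this stays open: over the 14 TG libraries Spearman's rho with the human transcript was -0.024 (permutation p = 0.938) and Pearson's r 0.12 (permutation p = 0.711), or -0.19 without the 2 farthest libraries. The extent of the transgene is not given in the sources used here, and a biological effect of the transgene on this gene was not tested apart from it.

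Other splits of the same libraries were drawn, 100 per comparison with the real one. For genotype in naive rats 3 of 100 splits, the real one included, gave as many as the 6 calls. The highest of the others gave 734, which points to a structure of the samples that the groups do not explain. Since other splits reach such counts, the low share does not exclude chance for so few calls. For genotype in crush rats 2 of 100 splits gave as many as 2 calls (highest other 2), a share that rests on the human transcript, and for the average 2 of 100 gave as many as 4 (highest other 611, again a structure of the samples). In these genotype counts the human transcript is itself 1 of the calls, which the real groups fix beforehand. With p adjusted again without it, 3 of 100 splits gave as many as 5 calls in naive rats (highest other 734) and 2 of 100 as many as 3 for the average (highest other 611). In crush rats 0 calls were left, which 100 of 100 splits reached (highest other 2), so chance cannot be excluded there. For crush in wt rats 1 of 100 splits, the real one, gave 36 calls (highest other 3), so chance can be excluded at this share. That does not set the injury apart from the spiny neuron level, which differed between the wt groups. For crush in TG rats 1 of 100, the real one, gave 492 (highest other 391). Another split came near that count, and leaving out TG crush replicate 220 took it to 164. The share therefore does not exclude chance for the size of the TG count. For the interaction 6 of 100 splits gave as many as 1 call (highest other 1), so chance cannot be excluded for that count.

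Nr1d2 is listed because its interaction passed limma's test, at a log2 value of 0.46 (adjusted p = 0.00604). The call was lost without the libraries high in Slc17a7. Its mean was 66.6 RPM in TG naive and 85.6 in wt naive libraries, against 119 in TG crush and 110 in wt crush libraries. A different response to crush is thus not shown apart from the difference between the naive groups.

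Among 66 reported values checked in each of the 4 groups, 26 of 264 sets had 1 library far from the others, where about 13.2 are expected by chance. For the human TOR1A transcript these were wt naive replicate 202 at 0.459 RPKM, wt crush replicate 207 at 0.211 and TG crush replicate 226 at 48.4, against 62.8 to 65.5 in the other TG crush libraries. Rat Tor1a was low in TG crush replicate 223, at 2.41 RPKM against 3.01 to 3.32, as was Arntl, at 0.157 against 0.229 to 0.258. Pld6 was high in wt crush replicate 210 (0.685 RPKM), TG naive replicate 189 (0.903) and TG crush replicate 222 (0.396). LOC679594 was low in wt crush replicate 203 (90.6 RPKM) and TG crush replicate 223 (57.3) and high in TG naive replicate 189 (107). Gh1 was high in wt naive replicate 202 (1.03 RPKM), TG naive replicate 188 (8.76) and TG crush replicate 223 (21.2). Mmp14 was high in TG naive replicate 190 (2.02 RPKM), Rbm3 in TG crush replicate 214 (15.0) and Vgf in wt crush replicate 205 (31.9). In wt naive replicate 197 Bc1 (949 RPKM) and Bst2 (2.79) were high, and in wt naive replicate 201 Calr (84.9). In wt crush replicate 203 Ndufa8 was high (9.10 RPKM), Ppp1r15b was low (5.51) and the mitochondrial share was high (15.9%). Mt2A was low in wt crush replicate 210 (5.33 RPKM) and Banf1 high in wt crush replicate 205 (28.1), and wt naive replicate 198 had the most assigned reads of its group (37113346).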

How the results depend on the processing

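RPM, voom, the spiny neuron covariate and the omission of libraries high in Slc17a7 were chosen after seeing the data. No named gene or list reversed past the threshold in the alternatives run for it; lists had 6 each and no omission of single libraries. For genotype in naive rats (6 calls), no filter gave 3 genes, the compared groups alone 2, and omission of the libraries high in Slc17a7 2. For genotype in crush rats (2 calls), a pseudocount of 0.01, median-of-ratios rescaling, array weights, a fold of at least 1.2, RPM, the spiny neuron covariate and omission of the libraries high in Slc17a7 each gave 1, the compared groups alone 4 and 1 surrogate factor 163. For the genotype average (4 calls), the surrogate factor gave 7, RPM 7 and the omission 1. For crush in wt (36 calls), no filter gave 16, the stricter filter 5, rescaling 22, robust variances 16, array weights 1348, the surrogate factor 1682, the spiny neuron covariate 6 and the omission 9. For crush in TG (492 calls), the compared groups alone gave 75, array weights 1804, the surrogate factor 1219, a fold of at least 1.2 258, the covariate 1019 and the omission 126. For the interaction (1 call), array weights gave 2, the surrogate factor 167 and the omission 0 (385 genes with an unadjusted p under 0.05, limma). Fewer libraries enter under the omission, a stricter criterion under the fold, and the surrogate factor alters only the error of each change. For the others the cause was not tested. The share of higher calls for crush in TG was 24.6%, against 48.9% with rescaling and 49.1% with quantile normalization, and for crush in wt 27.8% against 40.9% with rescaling. Rescaling moved the median of all genes by less than 0.1 on the log2 scale in each contrast.

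Leaving out each library in turn gave 3 to 7 genes for genotype in naive rats, 1 to 3 in crush rats, 4 to 7 for the average, 9 to 304 for crush in wt, 164 to 1074 for crush in TG and 1 to 2 for the interaction. For crush in wt 23 of the 28 omissions moved the count by over 1.5 times, and 23 of the 36 calls had an adjusted p above 0.045; for crush in TG 10 of the 28 did. For crush in wt the highest counts came without wt naive replicate 196 (304) and TG crush replicate 223 (106), and for crush in TG without TG crush replicates 223 (1074) and 226 (983) and TG naive replicate 188 (1051). The list calls over the 6 contrasts were 72 with the preset correlation, 2 with an estimated one, both for the clock list, and 4 with fry. Rat Tor1a kept its direction and stayed below the threshold under the 7 alternatives run for it. The r between genotype effects ranged from -0.25 to -0.03 with a library left out. The alternatives for raw counts were not run, since the table holds RPKM. What depth limits, at 29151455 to 38407359 reads, was not tested apart from the number of libraries; changes of 1.2-fold were recovered in 40% of cases in the simulated naive comparison.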

Other observations

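Growth hormone and prolactin, hormones of the pituitary, were detected in some striatal libraries. Gh1 reached 41.9 RPM in TG crush replicate 223 with 11.3 for Prl, and 32.5 in wt crush replicate 205 with 6.45 for Prl, while wt naive replicate 196 held 0 reads of both genes. The cortical gene Slc17a7 was above 20 RPM in 3 of 8 wt naive, 0 of 6 wt crush, 1 of 8 TG naive and 1 of 6 TG crush libraries, with 63.3 in TG crush replicate 220. Transthyretin (Ttr), abundant in choroid plexus, ranged from 2.57 RPM in TG naive replicate 189 to 126 in TG naive replicate 194.

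LOC500476 was either at most at 0.564 or above 10 RPM in each library. It was above 10 in 2 of 8 wt naive and 5 of 8 TG naive libraries. It stood at 13.4 to 26.3 in the 6 wt crush libraries and at 25.2 in TG crush replicate 214, and between 0.0620 and 0.140 in the other TG crush libraries.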
